A study of Arabidopsis thaliana with 12 samples.

How the data were processed

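Whole Arabidopsis thaliana plants of wild type Columbia and of nlp2-2 were compared, per the labels. They spent 4 days on 1/2-strength Murashige and Skoog plates and 10 days on nitrate-free plates that supplied nitrogen as ammonium succinate (2.5 mM) together with glutamine (0.5 mM), under 16 h light and 8 h dark. They were then kept for 1 h in nitrate-free solution with 0.5 mM ammonium succinate and 0.5% sucrose before 10 mM KNO3 or KCl was added for 1 h. Cy3-labelled cRNA was made from 200 ng RNA. Groups and replicate numbers come from the sample titles, with 3 arrays in each of 4 groups.

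The deposited scanner files hold spot intensity from Agilent Feature Extraction 9.1.3.1, and per the file headers the processed intensity was background-subtracted and detrended, with small substitute values for spots near or below background. The authors' series table holds a linear ratio of each spot to its array. Set against the scanner files, this deposited ratio was the processed intensity divided by the 75th percentile over all 45220 spots of the array. Spots at 0 in it were all not well above background, but other such spots kept a ratio above 0. Over spots above 0, log2 values of both correlated with r = 1, and column medians lay between 0.175 and 0.182. No genes were centred in it. Its values were used only as an alternative.

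From the scanner files, log2 of the processed intensity minus the 75th percentile of each array over probes that are not controls was computed, with the 5 spots of the 50 repeated probes averaged. Of 43603 such probes 38413 named a locus, covering 29030 loci, of which 28595 were found in the gene table of assembly TAIR10.1, used for names and for which genes neighbour each other. A locus with several probes (7320 loci) was represented by the probe with the highest mean signal, and probes without a locus were kept as features of their own. A probe entered if it was well above background on all 3 arrays of at least 1 group, which 32765 probes did. This left 24503 features, 21876 of them loci and 2627 without a locus. Among 6372 genes with several tested probes, 2 had probes called in opposite directions for the genotype difference in KNO3 and 2 for the mean nitrate response, and 0 did for the other comparisons. Median signals lay between 329 and 446 per array. The SD of negative controls was widest on wild type KNO3 replicate 1 (5.95) and wild type KCl replicate 3 (4.10), and 2.14 to 2.85 on the others.

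Means of the 4 groups were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and a prior of 2.04, because 3 arrays per group alone give few. The contrasts were the nitrate response of each genotype, their difference, the genotype difference in each salt and the mean nitrate response. A feature passed at a Benjamini-Hochberg adjusted p under 0.05, and counts with at least a 2-fold change were made too. The relative size of the response was tested over genes past 2-fold in the mean response, by an exact permutation test over the 400 arrangements of genotype labels within each salt, with the gene set held fixed. Where a gene was not well above background on any array of a group, the ratio is a bound: the brighter group's mean is set against the mean, per array, of the higher of the lowest signal among probes well above background and the gene's own signal. Such genes are given as "at least" a fold.

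The 16 gene lists were nitrate transport, nitrate reduction and ammonium assimilation, reductant supply, the NLP family, nitrate-signalling regulators, cytokinin, class III glutaredoxins, ammonium and organic nitrogen, carbon skeleton supply, phosphate starvation, anthocyanin and flavonoid, circadian clock, touch and wounding, shoot markers, root markers and reference genes. The last lists check handling, harvest time, the makeup of whole plants and scaling. They were tested in 5 contrasts, 80 tests in all, with camera in limma at a preset correlation of 0.01 and with an estimated correlation, both with Benjamini-Hochberg adjustment over the 80 tests. With the preset correlation 21 of 80 passed, with an estimated correlation 9, and with slide as a block 19. Medians, means and test directions of a list differed in sign for nitrate transport in both nitrate responses, the NLP family in both salts, class III glutaredoxins and clock genes in KCl, shoot markers for nitrate in wild type, phosphate starvation genes for the difference of responses, and shoot markers, phosphate starvation and reference genes in KNO3. The sign of a median changed with the scaling for nitrate transport and shoot markers in wild type, touch genes in nlp2-2, shoot markers, cytokinin, phosphate and ammonium genes for the difference of responses, and shoot markers, reference and clock genes in KNO3. A further 3 lists (salicylic acid and immune signalling, jasmonate response, iron deficiency) were written after the data had been seen, and are given as medians and counts of genes only, since such a list cannot test the pattern it was chosen for.

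Named genes follow a rule: NLP2 and its family; for each contrast the 8 highest and 8 lowest log2 differences among features past the threshold that carry a symbol or locus and were above background on all 3 arrays of a compared group, or the 5 smallest p-values where fewer than 3 passed; and in each list the 4 members with the largest moderated t for the mean response together with every member past the threshold between genotypes. The text names fewer genes than this rule gives. Further list members are named as examples of their list. The groups, contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were normexp background (offset 50) on mean and background signals with quantile normalization, quantile normalization and median scaling of the processed signal, the authors' deposited ratio, no filter and a stricter filter on dim probes, the mean over probes of a gene, each NLP2 probe apart, slide as a block (slide, scan and replicate number coincide), a variance trend, only the arrays compared, other fold minimums, and each array left out in turn. Leaving out the 2 arrays with the widest negative controls was added later.

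The tests were tested on simulated data with 10 sets of 200 changed genes among 24503. At 2-fold 89.9% were recovered for the wild type response, 90.6% for the nlp2-2 response, 81.2% for the difference of responses, 89.6% and 89% for the genotype difference in KCl and KNO3, and 95.4% for the mean response, with 4.36% to 5.47% of calls false. Camera at the preset correlation passed 1 of 10 sets with no list moved and 10 of 10 with the reductant supply list moved by 0.5. The simulated genes varied independently of each other, and adjustment was over 16 lists in 1 contrast. In the real data the estimated correlation was 0.159 for reductant supply and 0.277 for touch and wounding genes. These sets therefore cannot show that the preset correlation limits false calls. The permutation test of the relative response passed 3 of 10 sets in which nlp2-2 responded at 80% of wild type, and 1 of 10 with equal responses. Control spots were left out, saturated spots would have been kept, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.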

Results

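Transcript levels were measured with 12 one-colour Agilent arrays in whole Arabidopsis thaliana plants of wild type Columbia and of the mutant line nlp2-2. NLP2 (NIN-LIKE PROTEIN 2, AT4G35270) belongs to the plant family of RWP-RK transcription factors that act in nitrate signalling. After 4 days on 1/2-strength Murashige and Skoog plates, plants were grown for 10 days without nitrate, on ammonium succinate and glutamine, and then received 10 mM KNO3 or 10 mM KCl, the control salt, for 1 h. This gave 4 groups of 3 arrays. Between 69.3% and 77.5% of the probes that are not controls were well above background on each array, no spot was saturated, and the number of arrays limits the precision. Arrays of 1 group correlated with r between 0.992 and 0.998 across probes, and the lowest r between arrays of different groups was 0.984. Each of 3 slides carried 1 array of every group, and values with slide as a block are given beside those of the fit without it. Each group sat at a position of its own on every slide, so position and group cannot be told apart. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Values are log2 signals minus the 75th percentile of the array, errors of differences are standard errors (SE) from limma with 3 arrays per group, and adjusted p-values are those of limma with Benjamini-Hochberg adjustment over 24503 features, unless named otherwise.

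The NLP2 transcript was low on all 6 nlp2-2 arrays. In KCl its level was 0.02 ± 0.11 (SD, n = 3) in wild type and -3.21 ± 0.09 (SD, n = 3) in nlp2-2, and in KNO3 the levels were -0.27 ± 0.07 and -3.03 ± 0.16. The difference was -3.23 (SE 0.088, 9.38-fold, adjusted p = 1.23e-07 in limma) in KCl and -2.76 (SE 0.088, 6.76-fold, adjusted p = 5.94e-07 in limma) in KNO3, so 10.7% and 14.8% of the wild type signal remained. Within slides it ran from -3.31 to -3.08 in KCl and from -2.94 to -2.64 in KNO3, and with slide as a block the adjusted p-values were 1.2e-05 and 4.23e-05. The other NLP2 probe differed by -3.29 and -2.97. The remaining signal was well above background on every array, and the position of the lesion relative to the probes is not given in the sources used here. Nitrate itself did not move NLP2 past the test in wild type (-0.29, adjusted p = 0.135) or in nlp2-2 (0.18, adjusted p = 0.334).

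**Figure D1:**
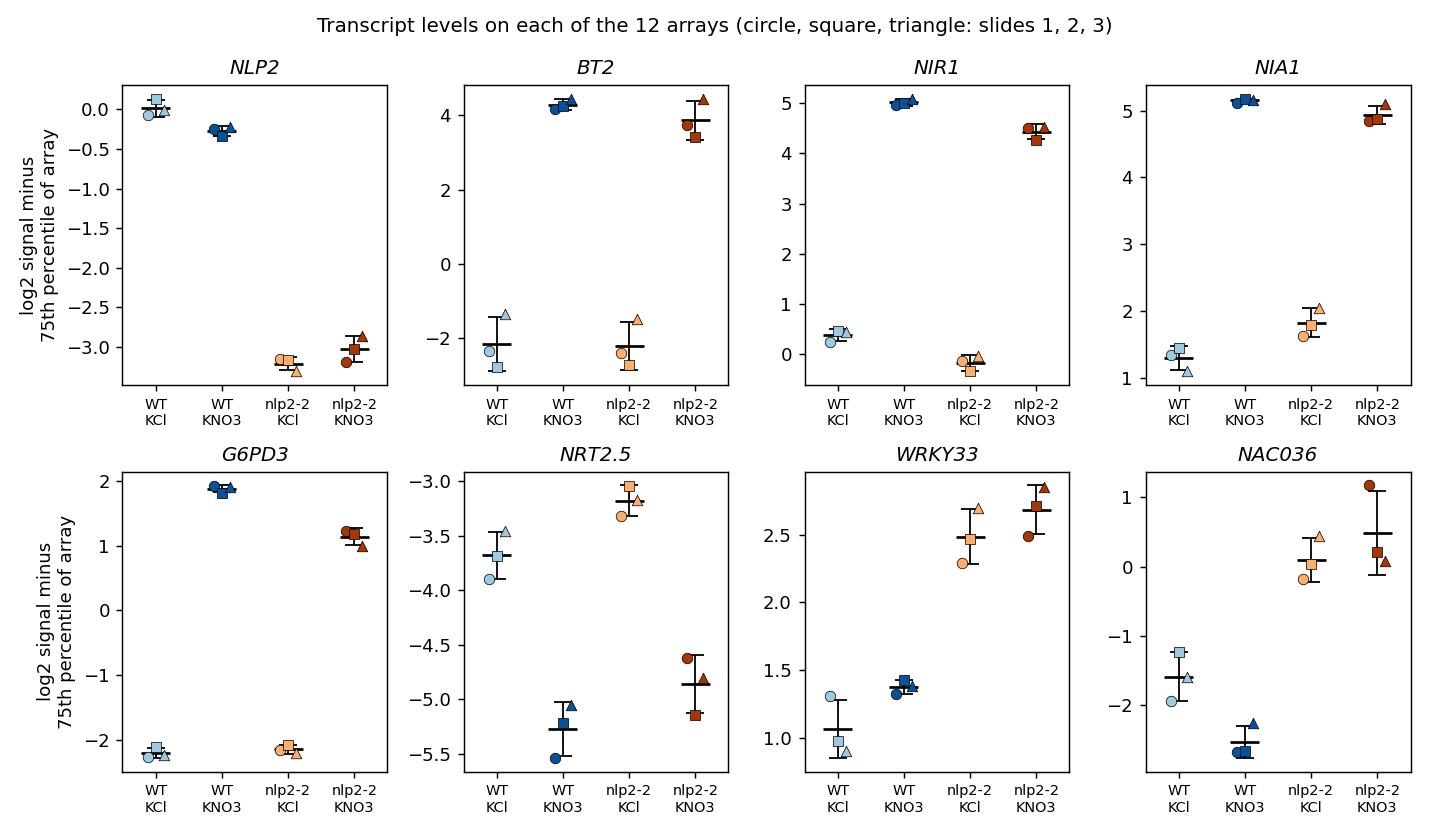
Level of 8 transcripts on each of the 12 arrays, as log2 signal minus the 75th percentile of the array (vertical axis, a separate scale for each gene), by genotype and salt (horizontal axis); symbols mark slides 1, 2 and 3, black lines the group mean and bars the SD of 3 arrays. NLP2 lies near -3.21 and -3.03 in nlp2-2, BT2, NIR1, NIA1 and G6PD3 are higher and NRT2.5 lower in KNO3 in both genotypes, and WRKY33 and NAC036 are higher in nlp2-2.

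The largest rises in wild type plants after nitrate included genes of nitrate reduction and of nitrate signalling. BT2 (AT3G48360), a BTB and TAZ domain protein, rose by 6.45 on the log2 scale (SE 0.41, adjusted p = 6.31e-06), from -2.16 ± 0.73 to 4.29 ± 0.15 (SD, n = 3). NIR1 (AT2G15620), the nitrite reductase, rose by 4.65 (SE 0.10, adjusted p = 1.87e-09), and NIA1 (AT1G77760), a nitrate reductase, by 3.86 (SE 0.12, adjusted p = 2.3e-08). G6PD3 (AT1G24280), a glucose-6-phosphate dehydrogenase of plastids, rose by 4.07 (SE 0.072, adjusted p = 8.23e-10). The GARP-type repressors HHO1 and HRS1 rose by 5.56 and 3.89, with HHO1 above background on only 1 of 3 wild type KCl arrays. BT1 rose by 4.36 and AT2G21210 by 4.44. UMAMIT35 was at least 6.22-fold higher in KNO3 (adjusted p = 0.000622), because it was not well above background on any wild type KCl array. The strongest falls were smaller. Among the genes past 2-fold in the mean response, AT2G28980 (-2.08) and ACS5 (-1.88) were lowest in wild type, but their test in wild type alone is not given here. RL5 fell by 1.82 (SE 0.25, adjusted p = 0.00223), AT4G17670 by 1.68, and AT5G49120 by 1.66 and ATGLR1.2 by 1.63, these last with 1 of 3 KNO3 arrays above background. AT1G64590 fell 3.02-fold. NRT2.5, a high-affinity nitrate transporter of nitrogen-starved plants, fell by 1.59 (SE 0.17, adjusted p = 0.000332).

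By gene list, the wild type response rose in 4 lists of nitrate use. Of 11 genes of reductant supply 9 rose and 0 fell, with the same counts adjusted over the list alone and a median of 1.36 (camera adjusted p = 1.07e-29), among them PGD3 (2.34), G6PD2 (2.03) and PGD1 (1.27). Of 11 class III glutaredoxins 7 rose and 0 fell, again also adjusted over the list alone, with a median of 2.12 (2.75e-13), with GRXS8 (3.81), GRXS4 (3.26), GRXS7 (2.99) and GRXS5 (2.88) the highest. Of 30 nitrate-signalling regulators 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.72 (3.31e-29), CIPK3 rising by 2.79, LBD37 by 2.39, and HHO6 falling by 0.49. Of 20 genes of nitrate reduction and ammonium assimilation 9 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.27 (3.72e-16), including the siroheme synthesis gene UPM1 (8.58-fold) and the asparagine synthetase ASN2 (2.85). With an estimated correlation these 4 calls held at adjusted p-values of 0.00485, 0.00941, 0.00823 and 0.00823. Nitrate transport was mixed: 5 of 20 genes rose, among them NRT2.1 (2.82-fold), its partner NRT3.1 (1.03), NRT1.1 (0.86) and CLCA (0.65), a nitrate/proton exchanger of the vacuole,, and NRT2.5 fell (5 and 5 adjusted over the list alone). That list's camera test did not pass (adjusted p = 0.0984). In the NLP family NLP3 (0.59) and NLP1 (0.36) rose, while NLP5 (-0.99), NLP4 (-0.98), NLP9 (-0.36) and NLP8 (-0.31) fell (2 and 5 adjusted over the list alone, median -0.29, camera adjusted p = 0.0117), a call lost at adjusted p = 0.152 with an estimated correlation.

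Altogether 872 features passed in wild type, 516 higher and 356 lower in KNO3, and 219 of them changed at least 2-fold, 172 up and 47 down. With slide as a block 904 passed, and within slides BT2 rose by 5.81 to 7.04 and NIR1 by 4.56 to 4.73. Only 562 passed without wild type KNO3 replicate 2, and the lower count fell to 168 without wild type KCl replicate 2.

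In nlp2-2 genes of nitrate reduction and signalling were again among the largest rises. BT2 rose by 6.07 (SE 0.41, adjusted p = 1.57e-05), HHO1 by 5.22, NIR1 by 4.62 (SE 0.10, adjusted p = 2.92e-09) and BT1 by 4.36. HRS1 rose by 3.75, G6PD3 by 3.27 (SE 0.072, adjusted p = 2.92e-09) and NIA1 by 3.11 (SE 0.12, adjusted p = 2e-07). DIN11 rose by 4.16 (SE 0.47, adjusted p = 0.000851). UMAMIT35 was at least 7.35-fold and AT2G48080 at least 13.6-fold higher in KNO3, neither being well above background on any nlp2-2 KCl array. NRT2.5 fell by 1.68 (SE 0.17, adjusted p = 0.000326), AT5G67430 by 1.45 and AT4G17670 by 1.42, and AT3G55180, ACS5 and AT5G57400 were at least 1.74-fold, 1.67-fold and 2.85-fold lower in KNO3.

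The same 4 lists rose in nlp2-2. For reductant supply 9 of 11 genes rose and 0 fell, with the same counts adjusted over the list alone (median 0.92, camera adjusted p = 1.14e-22), including PGD3 (3.26-fold) and G6PD2 (1.55). For class III glutaredoxins 7 of 11 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.61, 2.71e-11), with GRXS8 at 3.18 and GRXS5 at 1.94. For nitrate-signalling regulators 18 of 30 rose and 1 fell (21 and 2 adjusted over the list alone, median 0.58, 3.7e-23), with CIPK3 at 2.57 and LBD37 at 1.93. For nitrate reduction and ammonium assimilation 7 of 20 rose and GLN1;1 fell by 0.27 (10 and 1 adjusted over the list alone, median 0.19, 2.5e-10), with UPM1 at 2.92 and ASN2 at 2.52. With an estimated correlation the adjusted p-values of these lists were 0.00681, 0.0142, 0.00941 and 0.0203. Nitrate transport again did not pass (0.421), with NRT2.1 (2.64-fold) and CLCA (0.63) among 4 genes that rose and NRT2.4 (-1.13) and NRT2.5 the genes that fell (6 and 2 adjusted over the list alone). In the NLP family 0 genes rose, and NLP5 (-0.92), NLP4 (-0.75) and NLP8 (-0.39) fell (1 and 3 adjusted over the list alone, median -0.09, camera adjusted p = 0.0441). That call ended with slide as a block (adjusted p = 0.0545) and was lost at adjusted p = 0.224 with an estimated correlation.

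In nlp2-2 722 features passed, 460 higher and 262 lower in KNO3, and 151 changed at least 2-fold, 127 up and 24 down; with slide as a block 716 passed. Without nlp2-2 KCl replicate 1 only 352 passed. Both genotypes shared 333 features called higher, where 9.69 are given by independent lists, and 132 called lower, where 3.81 are. These comparisons share no arrays but take their spread from 1 fit over all 12, so their calls are not independent.

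Whether the response to nitrate depends on NLP2 is asked directly by the difference between both responses, written here as nlp2-2 minus wild type. The largest evidence for single genes was for KNAT4 (AT5G11060), a KNOX homeobox gene, at 0.62 (SE 0.074, adjusted p = 0.115), and for G6PD3 at -0.80 (SE 0.10, adjusted p = 0.115). They were followed by SAG21 at -0.97 (SE 0.14, adjusted p = 0.211), PGD3 at -0.64 (SE 0.093, adjusted p = 0.211) and ECT6 at 0.39 (SE 0.059, adjusted p = 0.244). None of these 5 genes, the ones with the smallest p-values, passed. Within slides G6PD3 ran from -0.94 to -0.67 and KNAT4 from 0.55 to 0.72. NIA1 differed by -0.75 (adjusted p = 0.511), while NIR1 (-0.03) and BT1 (-0.01) lay close to 0. Part of the NIA1 value lies in KCl, where its level was 1.62 to 2.05 in nlp2-2 and 1.09 to 1.44 in wild type. In KNO3 its level was 4.84 to 5.09 in nlp2-2 and 5.12 to 5.17 in wild type. In limma 0 features passed for the difference of responses, with or without slide as a block, and 1170 had an unadjusted p under 0.05. On simulated data with 200 changed genes per set the same test recovered 81.2% of 2-fold and 48.1% of 1.5-fold differences. With fewer changed genes the adjustment asks for a smaller p, so these shares need not hold here. G6PD3, at -0.80 with an SE of 0.10, did not pass.

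Of the gene lists, 4 responded less in nlp2-2 by camera at the preset correlation. Reductant supply had a median difference of -0.47 (camera adjusted p = 2.3e-17), and its adjusted p with an estimated correlation was 0.00823. Within slides the median ran from -0.52 to -0.31, and with slide as a block the adjusted p was 1.02e-15. Adjusted over the list alone, 8 of its 11 genes had a smaller response in nlp2-2, among them G6PD3, PGD3, RFNR1 (-0.68), RFNR2 (-0.68), FD3 (-0.50) and G6PD2 (-0.47), whereas 0 passed over all genes. RFNR1, RFNR2 and FD3 encode the ferredoxin and ferredoxin reductases of non-green plastids. Class III glutaredoxins had a median of -0.42 (camera adjusted p = 0.00441; adjusted p = 0.224 with an estimated correlation; 2 of 11 lower adjusted over the list alone), within slides -0.65 to -0.17. Nitrate-signalling regulators had a median of -0.12 (0.00014; adjusted p = 0.234 with an estimated correlation; 3 of 30 lower adjusted over the list alone), within slides -0.10 to -0.09. Nitrate reduction and ammonium assimilation had a median of -0.11 (1.87e-05; adjusted p = 0.105 with an estimated correlation; NIA1 and GLT1 lower adjusted over the list alone), within slides -0.12 to -0.07. With slide as a block these adjusted p-values were 0.0157, 1.74e-05 and 8.07e-05. Nitrate transport did not pass (median -0.09, adjusted p = 0.154). Camera compares a list with all other genes and not with other induced genes, so these calls do not set the 4 lists apart from the rest of the response.

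Over both genotypes together, 1932 features passed for the mean nitrate response, 992 higher and 940 lower, of which 184 changed at least 2-fold. Without nlp2-2 KCl replicates 1 and 2 in turn 1275 and 1271 passed, 591 and 582 of them lower. This selection does not favour either genotype. Of its 154 induced genes 128 (83.1%) had a smaller response in nlp2-2, with median responses of 1.65 in wild type and 1.45 in nlp2-2 and a median difference of -0.31, which did not pass an exact permutation test (two-sided p = 0.085 over 400 arrangements of the genotype labels). Within slides the median was -0.27, -0.27 and -0.38, and with slide as a block it was -0.31 (exact permutation p = 0.25 over 64 arrangements). Without wild type KCl replicate 2 the exact permutation p was 0.04. The induced genes differed between genotypes by a median of only -0.03 in KCl. Labels were rearranged in each salt apart, so a shortfall that lies in KNO3 alone recurs under arrangements of the KCl labels. The test therefore had little chance to pass, and its miss says little about the shortfall. Of the 30 repressed genes 21 (70%) had a smaller response in nlp2-2, with a median difference of 0.14 (exact permutation p = 0.455).

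**Figure D2:**
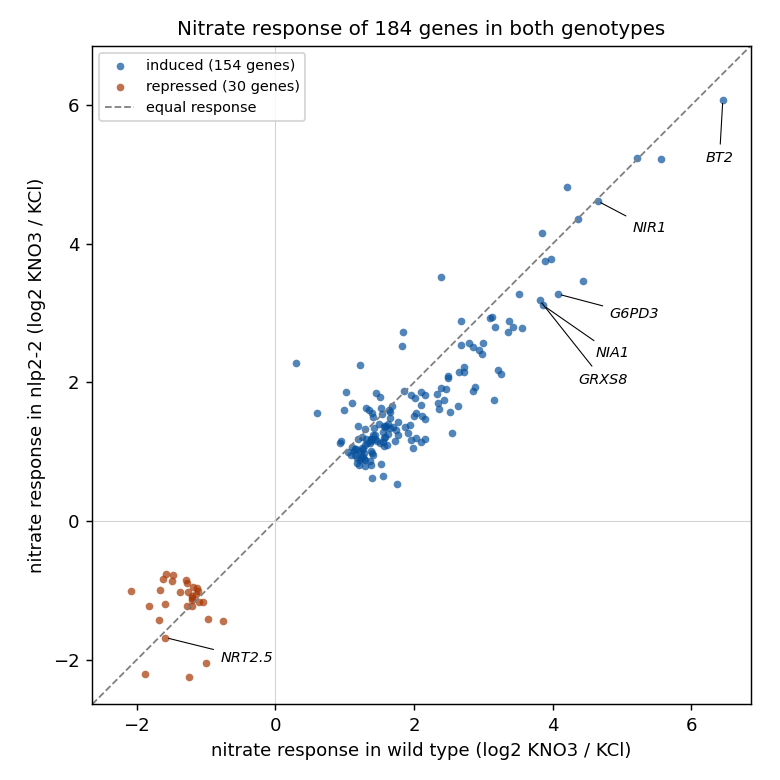
Nitrate response in nlp2-2 (vertical axis) against that in wild type (horizontal axis), both as log2 ratio of KNO3 to KCl, for the 154 induced (blue) and 30 repressed (brown) genes past 2-fold in the mean of both genotypes; each point is 1 gene and the dashed line marks an equal response. 128 of the induced genes lie on the side of a smaller response in nlp2-2, G6PD3 at 4.07 and 3.27 among them, while NIR1 lies close to the line at 4.65 and 4.62.

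After 1 h of KCl, the control salt, genes known from defence and touch responses were among those higher in nlp2-2 than in wild type. WRKY33 (AT2G38470), a defence transcription factor, was higher by 1.42 (SE 0.13, adjusted p = 0.000528), and CML41 (AT3G50770), a calmodulin-like protein, by 2.28 (SE 0.18, adjusted p = 0.000286). AT2G04495 was higher by 3.31 (SE 0.43, adjusted p = 0.00283) and AT1G76210 by 3.04, with 1 and 2 of 3 wild type arrays above background. AT5G38910 was higher by 2.62 (SE 0.45, adjusted p = 0.0112), AT1G78410 by 2.39 and AT3G48650 by 2.37. CKX2, a cytokinin oxidase, and PCR1 were at least 2.19-fold and 4.42-fold higher, not being well above background on any wild type KCl array. BHLH100, of the iron deficiency response, was higher by 6.12 (SE 1.45, adjusted p = 0.0445), but only 1 of 3 wild type arrays had it above background, slides gave 1.73 to 8.36, and the call ended with slide as a block (adjusted p = 0.0613). AT1G71000 was at least 2.18-fold lower (adjusted p = 0.0305). ARR15, a type-A response regulator of cytokinin signalling, was lower (-1.01, SE 0.10, adjusted p = 0.000741), as were AT3G28270 (-1.40), CHAT (-1.27) and AT1G70390 (-1.25). COR15B (-0.97) and AT1G70270 (-1.03) were called lower, but not with slide as a block (adjusted p = 0.059 and 0.0706). Of 20 genes of nitrate reduction and ammonium assimilation 4 were higher and 2 lower in KCl (6 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.082). NIA1 (0.53), GLN1;2 (0.31), GLU2 (0.27) and GLN1;1 (0.26) were higher, and NIR1 (-0.56, SE 0.10, adjusted p = 0.0135) and UPM1 (-0.32) lower. The calls of NIA1, GLN1;2 and UPM1 ended with slide as a block (adjusted p = 0.0502, 0.0571 and 0.0517). NRT1.4 (-0.41) and NLP9 (-0.37) were lower too.

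Of the 14 tested touch and wounding genes 6 were higher in nlp2-2 KCl and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 6.18e-09), within slides 0.62 to 1.01. This call was lost at adjusted p = 0.105 with an estimated correlation, and held with slide as a block (4.28e-08). The 6 genes were WRKY33, ERF104 (1.42), ERF6 (1.16), ZAT10 (1.15), TCH3 (0.89) and ERF5 (0.86). The 14 anthocyanin and flavonoid genes had a median of -0.43 (camera adjusted p = 0.000201), within slides -0.63 to -0.21, a call lost at adjusted p = 0.31 with an estimated correlation. Of these genes 0 were called over all genes and 7 were lower adjusted over the list alone, DFR at -1.24 (adjusted p = 0.0585). Reductant supply, whose genes responded less, had a median of 0.02 in KCl (0.393, 0 called, also adjusted over the list alone). Shoot markers (-0.06), root markers (0.01) and reference genes (0.00) gave no call in KCl, with camera adjusted p-values of 0.531, 0.864 and 0.864.

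In KCl 1107 features passed, 728 higher and 379 lower in nlp2-2, and of 180 with at least a 2-fold change 172 were higher and 8 lower. With slide as a block 1181 passed. The count fell to 466 without nlp2-2 KCl replicate 1, and to 630 when only the 6 KCl arrays entered the fit.

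In KNO3 genes known from defence and touch responses were again among those higher in nlp2-2, and several genes of the nitrate response were lower. NAC036 (AT2G17040), a NAC transcription factor, was higher by 3.01 (SE 0.29, adjusted p = 0.00036), with levels of -2.53 ± 0.23 in wild type and 0.49 ± 0.60 in nlp2-2 (SD, n = 3). AT5G52760 was higher by 2.72 (SE 0.24, adjusted p = 0.000193), AT1G35710 by 2.67 (SE 0.21, adjusted p = 0.000111) and WRKY33 by 1.31 (SE 0.13, adjusted p = 0.000441). NIMIN1, an interactor of the salicylic acid regulator NPR1, was higher by 3.01 (SE 0.63, adjusted p = 0.0174), with 2 of 3 wild type arrays above background. AT2G04495 was at least 5.47-fold and CKX2 at least 1.98-fold higher, and AT1G76210 was higher by 2.80, with 1 of 3 wild type arrays above background. The peptide genes CLE4 (-1.71, SE 0.13, adjusted p = 0.000104) and CLE7 (-1.41, SE 0.27, adjusted p = 0.0125) were lower, as were AT1G70390 (-2.13, with 1 of 3 nlp2-2 arrays above background), AT1G20180 (-1.48), G6PD3 (-0.74, SE 0.072, adjusted p = 0.000362), PGD3 (-0.62), NIR1 (-0.59), UPM1 (-0.50), ASN2 (-0.49), GRXS6 (-0.77) and GRXS8 (-0.72). Smaller falls were seen for NRT3.1 (-0.35), IPT3 (-0.35), a gene of cytokinin synthesis, and NRT2.1 (-0.33), while NLP4 (0.39) and NLP5 (0.30) were higher. In all, 1 of 20 nitrate transport genes was called higher and 2 lower. For nitrate reduction and ammonium assimilation 1 of 20 was called higher and 3 lower. AT5G49050 (-3.06) and GRXS1 (1.44) were called on few arrays above background, and both calls ended with slide as a block (adjusted p = 0.0578 and 0.0692).

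Of 11 genes of reductant supply 8 were lower in nlp2-2 KNO3 and 0 higher, with the same counts adjusted over the list alone (median -0.38, camera adjusted p = 2.32e-07, within slides -0.44 to -0.34). This call was lost at adjusted p = 0.0551 with an estimated correlation, and it held with slide as a block (6.99e-07). Of the touch and wounding genes 7 were higher and 0 lower (10 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 5.11e-07), within slides 0.63 to 0.74. This call was lost at adjusted p = 0.152 with an estimated correlation, and held with slide as a block (2.02e-06). The 7 genes included ERF6 (1.27), TCH4 (2.16-fold) and ZAT10 (1.02). No other list passed in KNO3: adjusted p was 0.0733 for anthocyanin and flavonoid genes (median -0.23), 0.0984 for nitrate-signalling regulators, 0.134 for class III glutaredoxins, 0.341 for nitrate reduction and ammonium assimilation and 0.393 for nitrate transport. Shoot markers (-0.02, 0.939), root markers (0.04, 0.901) and reference genes (-0.01, 0.626) gave no call, and the sign of the shoot and reference medians changed under other scalings.

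In KNO3 2220 features passed, 1266 higher and 954 lower, and of 290 with at least a 2-fold change 258 were higher and 32 lower. With slide as a block 2279 passed, whereas 1035 passed without wild type KNO3 replicate 2 and 891 with only the 6 KNO3 arrays in the fit. In both salts 597 features were called higher in nlp2-2, where independent lists give 37.6, and 170 lower, where they give 14.8. The same limit holds for these calls.

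The other lists changed little. The cytokinin list passed in nlp2-2 at the preset correlation (median 0.17, camera adjusted p = 0.0118), a call lost at adjusted p = 0.144 with an estimated correlation, and only IPT3 (1.42) and ARR8 (0.61) rose of 22 genes (4 and 1 adjusted over the list alone). In wild type the same list had a median of 0.17 (0.0654; IPT3 1.76, ARR8 0.55, CKX6 -0.65; 6 and 2 adjusted over the list alone), and between genotypes it did not pass in KCl (-0.17, 0.0551) or KNO3 (-0.11, 0.156). The clock list passed in nlp2-2 at the preset correlation (median 0.16, camera adjusted p = 0.0117), a call lost at adjusted p = 0.161 with an estimated correlation, and of 11 genes only LUX (0.45) and ELF3 (0.23) were called higher and ELF4 (-0.40) lower (3 and 1 adjusted over the list alone). In wild type clock genes did not pass (0.082). The ELF3 call ended with slide as a block (adjusted p = 0.0537). The phosphate starvation list passed in wild type at the preset correlation (median -0.14, camera adjusted p = 0.0468), but 0 of its 16 genes fell and PHR1 (AT4G28610, 0.49) rose (1 and 5 adjusted over the list alone). That call ended with slide as a block (adjusted p = 0.0521) and was lost at adjusted p = 0.337 with an estimated correlation. In nlp2-2 the phosphate list did not pass (0.124; PHR1 0.33, PHT1;4 -0.46). Ammonium and organic nitrogen genes did not pass in wild type (median -0.22, 0.082) or nlp2-2 (-0.25, 0.07), with AMT1;1 (-0.50) called in wild type only without the slide block (adjusted p = 0.0628 with it). Carbon skeleton supply did not pass (0.259 and 0.626), although PPC2, a phosphoenolpyruvate carboxylase, rose by 0.82 in wild type and 0.94 in nlp2-2. Anthocyanin and flavonoid genes did not pass for nitrate (0.136 and 0.776), with MYB90 falling by 0.84 and 0.95 and MYB12 called lower too (-0.29 and -0.41), in wild type only without the slide block (adjusted p = 0.075 with it). Touch and wounding genes did not pass for nitrate (0.187 and 0.614), nor did shoot markers (0.79 and 0.415), root markers (0.947 and 0.684, with SCR rising by 0.23 and 0.43) or reference genes (0.739 and 0.398).

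**Figure D3:**
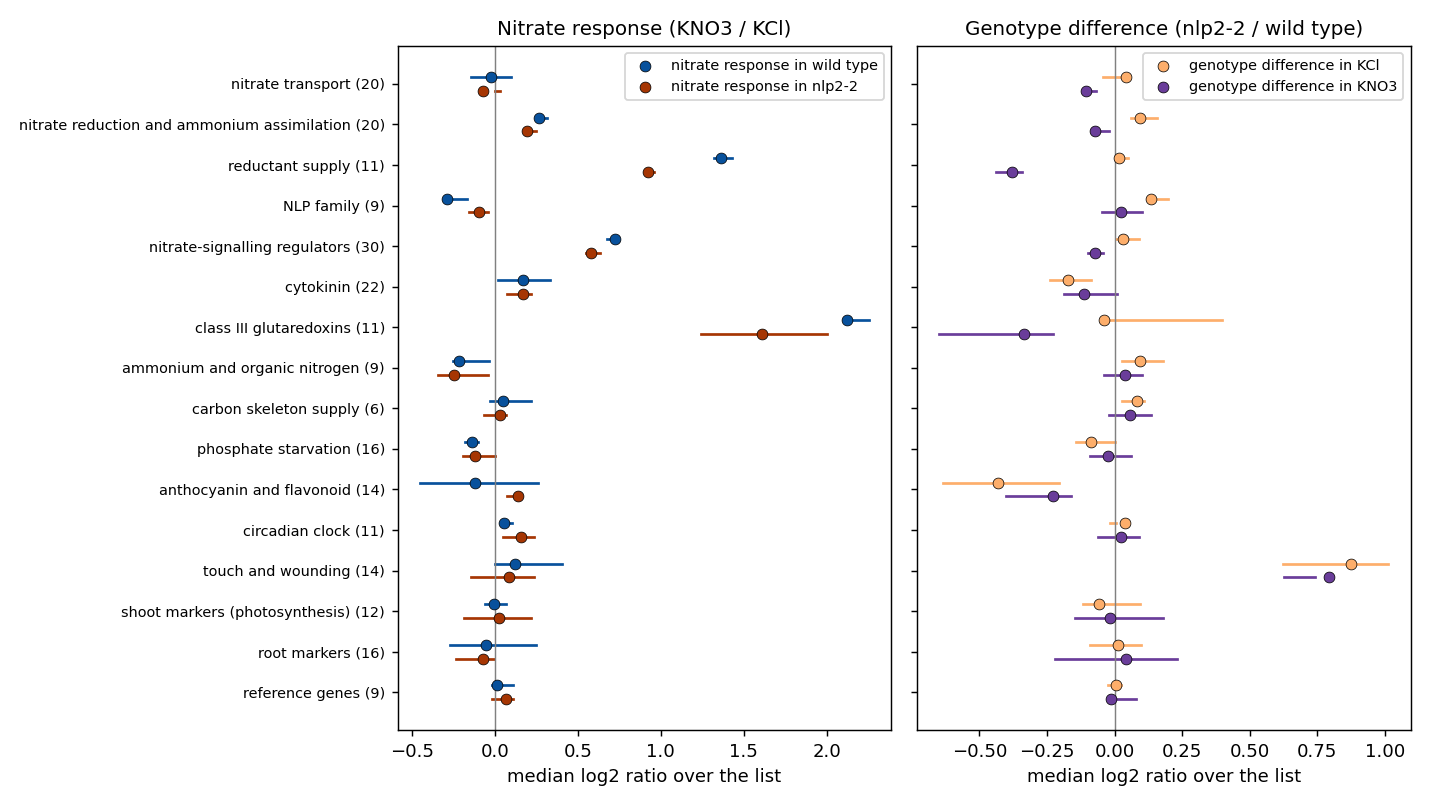
Median log2 ratio over each of the 16 gene lists (number of tested genes in brackets) for the nitrate response in both genotypes (left) and for nlp2-2 against wild type in both salts (right); points are medians over all arrays and lines run from the lowest to the highest of the 3 medians within slides, which need not include the point. Reductant supply lies at 1.36 in wild type and 0.92 in nlp2-2, touch and wounding genes lie at 0.87 and 0.79 between genotypes, and medians of nitrate transport in wild type, touch genes for nitrate in nlp2-2, and shoot, clock and reference genes near 0 change sign with the scaling.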

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

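Of the tests in this part, the comparison of spike-in slopes and that of starting levels within each list were chosen after the result was seen. The test of the difference between both nitrate responses singled out 4 gene lists, each with a smaller response in nlp2-2: reductant supply (median -0.474), class III glutaredoxins (-0.420), nitrate-signalling regulators (-0.122) and nitrate reduction and ammonium assimilation (-0.107). With an estimated correlation only the first of these passed. Over the 154 induced genes the median of -0.31 missed the exact permutation test (p = 0.085), which says little about a shortfall in KNO3 alone. Their median shortfall was 19% of the median wild type response. Camera sets a list against all other genes, so its calls do not show that these lists fell short more than other induced genes. A higher starting level in nlp2-2 KCl is argued against for the induced genes, which differed there by a median of -0.0343 (SD of slide medians 0.038) where at least 0.157 was needed, and for reductant supply (0.0164, SD 0.0226, needed 0.237). It stays open for class III glutaredoxins (-0.0384, SD 0.224, needed 0.21), where slide medians ran from -0.0272 to 0.397 and the highest lay above the needed value. It also stays open for regulators (0.0315, SD 0.0427, needed 0.0609). Nitrate reduction and ammonium assimilation had a higher median in nlp2-2 KCl (0.0935, camera adjusted p = 0.082, within slides 0.0593 to 0.158, needed 0.0536). A higher starting level may therefore account for part of that list's smaller response, although the KCl arrays enter both values. For the induced genes, compression of the log scale on nlp2-2 arrays is argued against by the spike-in slopes. The ratio of the mean slope of nlp2-2 KNO3 arrays to that of wild type KNO3 arrays was 0.982, where 0.905 or less was needed. The larger SD of the slopes within these groups, that of wild type KNO3, was 0.0203. A single array is argued against by the median staying below 0 without each array and within each slide (highest value -0.265). Open remain the position on the slide, which cannot be told apart from the group, chance for the induced genes as a whole, and the hypothesis that NLP2 itself may set part of the response of reductant genes, which this design cannot separate from other changes in the line.

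For the number of features past the threshold, other splits of the arrays were counted. For the difference of responses the real count was 0, which any split reaches (100 of 100 drawn, highest other 1), so this count decides nothing about chance. For the mean nitrate response 1 of 100 drawn splits gave as many features, the real one (1932, highest other 15), so regrouping these arrays at random seldom gives such a count. Chance differences between plants or cultures are not tested by it, because the replicates may be technical. The other comparisons have 10 splits, too few for a share under 0.05. The real split was the 1 with as many features in each of them: 872 in wild type (highest other 23), 722 in nlp2-2 (highest other 0), 1107 between genotypes in KCl (0) and 2220 in KNO3 (0).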

How the results depend on the processing

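Leaving out the 2 arrays with the widest negative controls was chosen after seeing the data; all other alternatives were planned. No called result turned its direction, and no scaling moved the median of all features by over 0.1. Of 226 called results for named genes 142 held in every setting, 77 were lost in at least 1 alternative and 63 without at least 1 array; of 274 not called, 27 were gained somewhere. Samples share a replicate number with their slide, but only 11 of 18 same-slide pairs deviated together with r over 0.1 (-0.0124 to 0.381), and the numbers were treated as pairs only if all did. All 12 arrays correlated best with their own slide, and deviations had a mean r of 0.131 within slides and -0.0648 between them. Deviations were taken from group means, so a positive mean r within slides brings a negative one between slides, which adds no support. Arrays of 1 slide thus shared part of their deviation, by the data and not by the labels. Its source cannot be told, since slide, scan and replicate number coincide. The replicate block, which is the slide block, gave 904, 716, 0, 1181, 2279 and 2054 calls for the wild type response, nlp2-2 response, difference of responses, genotype in KCl, genotype in KNO3 and mean response, against 872, 722, 0, 1107, 2220 and 1932. Among named genes it also ended the calls of ARR16 (adjusted p = 0.0519) and GLN1;1 (0.0533) in KNO3. 

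With normexp and quantile normalization counts past 2-fold fell to 139 (wild type, from 219), 100 (nlp2-2, from 151), 163 (KNO3, from 290) and 117 (mean, from 184); the cause was not tested. Under it 4 genes passed for the difference of responses, all 4 lower and 2 past 2-fold: G6PD3 (-0.75), CLE4 (-1.10), AT2G22200 (-1.15) and AT5G24230 (-0.79), named here after their values were seen, with adjusted p from 0.0288 to 0.0338. Without a filter, which adds dim probes to the correction, the lower calls were 190 in wild type and 584 in the mean, nlp2-2 gave 447 (118 lower), KCl 553 (431 and 122) and KNO3 1229 (788 and 441). With only the arrays compared, and so fewer degrees of freedom, wild type gave 558 (188 lower), nlp2-2 458 (304 and 154), KCl 630 (447 and 183) and KNO3 891 (685 and 206). Without the 2 arrays wild type gave 501 (131 lower), KNO3 1241 (799 and 442) and the mean 585 lower; the cause was not tested. Camera with an estimated correlation passed 9 of the 80 tests of a list in a contrast, in place of 21. Median scaling split calls 584 to 191 in nlp2-2 (75.4% higher, main 63.7%), 1304 to 640 in KNO3 (67.1%, main 57%) and 1215 to 758 in the mean (61.6%, main 51.4%).

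Leaving out each array in turn gave, as lowest and highest, 562 and 937 for wild type (higher 386 and 536, lower 168 and 401, 2-fold 195 and 217), 352 and 711 for nlp2-2 (272 and 456, 77 and 262, 132 and 158), 466 and 1294 for KCl (389 and 782, 77 and 512, 111 and 201), 1035 and 2236 for KNO3 (727 and 1278, 308 and 958, 242 and 291), 1271 and 1931 for the mean (684 and 969, 582 and 962, 181 and 189), and 0 and 1 for the difference of responses, AT4G35510 (-0.64) passing without nlp2-2 KNO3 replicate 2. The induced median ran from -0.348 to -0.268 and its share from 79.1% to 86.5%. The repressed median ran from 0.0679 to 0.309 and its share from 51.9% to 75.7%. NLP2 ran from -3.27 to -3.17 in KCl and -2.84 to -2.68 in KNO3, and the number of list tests passing from 19 to 26. The induced genes passed at exact permutation p = 0.04 without wild type KCl replicate 2, over a range of 0.04 to 0.13. Counts moved over 1.5 times without these arrays. KCl gave 724 and 486 without wild type KCl replicates 1 and 2, and 466, 642 and 525 without nlp2-2 KCl replicates 1, 2 and 3; its lower calls 161, 88, 77, 171 and 134 in that order, and 198 without wild type KNO3 replicate 2; its higher calls 398 without wild type KCl replicate 2 and 389, 471 and 391 without nlp2-2 KCl replicates 1, 2 and 3; its 2-fold calls 111 without nlp2-2 KCl replicate 3. KNO3 gave 1232, 1035 and 1359 without wild type KNO3 replicates 1, 2 and 3 and 1449 without nlp2-2 KNO3 replicate 1 (lower 459, 308, 441 and 569, and 608 without nlp2-2 KCl replicate 1; higher 773 and 727 without wild type KNO3 replicates 1 and 2). Wild type gave 562 without wild type KNO3 replicate 2, with lower calls of 168, 176 and 176 without wild type KCl replicate 2 and wild type KNO3 replicates 1 and 2. The nlp2-2 response gave 352 and 362 without nlp2-2 KCl replicates 1 and 2 (higher 272 and 285, lower 80 and 77), and lower calls of 152, 169, 173 and 172 without nlp2-2 KCl replicate 3, wild type KNO3 replicate 2 and nlp2-2 KNO3 replicates 2 and 3. The mean gave 1275 and 1271 without nlp2-2 KCl replicates 1 and 2 (lower 591 and 582). The cause was not tested.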

Other observations

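In this part the marker lists, the genes named below, and the tests of plasmid left in a preparation, of plant makeup and of slide position were chosen after the result was seen, and the vector search was widened after it. Of 17 genes of salicylic acid and immune signalling 10 were higher in nlp2-2 in KCl and 9 in KNO3, 0 lower, with list medians of 0.84 and 0.84, within slides 0.60 to 1.00 and 0.57 to 1.07. Because the lists were chosen after the data were seen, no test of a list is given here. CBP60G and SARD1, transcription factors that act on salicylic acid synthesis, were higher by 1.88 and 1.21 in KCl and 2.19 and 1.38 in KNO3, FMO1 by 1.42 and 1.53, WRKY70 by 1.00 and 1.42, EDS1 by 0.64 and 0.85 and PAD4 by 0.53 and 0.60. PR2 (1.87) and PR5 (1.45) passed in KCl, while PR1 did not pass in either salt (0.84 and -0.35). ICS1 passed in KCl (0.53) but not in KNO3 (0.42). EDS5 (-0.005 and 0.19), PBS3 (0.45 and 0.24), SAG101 (0.28 and 0.12) and ALD1 (0.65 and -0.19) did not pass in either salt. The 10 jasmonate response genes had medians of 0.02 in both salts and 0 called.

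Of 14 tested genes of the iron deficiency response, IRT1 also among the root markers, BHLH100 and NAS2 (0.68) passed in KCl, with a list median of 1.02, within slides 0.43 to 1.45. In KNO3 only NAS2 (0.45) passed, with a median of 0.50, within slides 0.17 to 1.17. BHLH101 (2.33, adjusted p = 0.0731) and IRT1 (2.76, adjusted p = 0.138) did not pass in KCl. For nitrate the list had a median of 0.31 in wild type, within slides 0.08 to 0.57, and for the difference of responses -0.44, within slides -1.02 to 0.09.

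A pair of probes designed on expressed sequence tags, EG432265 and CO048493, whose sequences match common cloning vectors over 35 and 26 bases, were well above background on 6 of 6 nlp2-2 arrays and 0 of 6 wild type arrays, at least 104-fold and 3.25-fold higher in nlp2-2 in KCl and at least 80.6-fold and 2.44-fold in KNO3. Plasmid left in a single preparation is argued against by their brightness on 6 nlp2-2 arrays. Transcripts from vector sequence carried by the line are a candidate explanation, for which, as predicted beforehand, further matching probes should have been over 2-fold higher in both salts, and 0 were. The nearest, AT3G32377, was at 0.84 and 0.98 in KCl and KNO3 and did not pass (adjusted p = 0.119 and 0.0564), above background on 6 of 6 nlp2-2 and 4 of 6 wild type arrays. By that prediction the explanation would have been excluded, but it was left open after the result was seen: of 43603 probes 8 matched 11 plasmid parts over at least 15 bases, where chance gives 5.6, and beyond this pair 0 matched over 20 or more, a limit set afterwards, so the array may hold no other probe of vector sequence, and the labels do not say how the allele was made.

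The higher defence and touch transcripts in nlp2-2 were set against explanations other than the lost NLP2 transcript. Of the 100 genes around NLP2 15% (exact interval 8.65% to 23.5%) were called for a genotype difference, against 10.7% of others and 32% predicted for linked variants (Fisher's exact p = 0.191), but that prediction was wrong in that a linked variant acting on genes elsewhere need not alter its neighbours, so linked variants stay open. A shift between root and shoot is argued against by shoot and root marker medians of -0.0568 and 0.0112 in KCl (SD of slide medians 0.119 and 0.095), where 0.437 was needed, and of -0.0171 and 0.0411 in KNO3 (SD 0.166 and 0.226, root within slides -0.221 to 0.231), where 0.396 was needed. Position on the slide stays open, since 0 positions were shared by both genotypes, and so do variants elsewhere, handling of the plants and a biological effect of NLP2, which may or may not act on these genes and was not tested apart from the line.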
